A study of Drosophila melanogaster with 12 samples.

How the data were processed

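The study measured gene expression in heads of unmated Oregon-R males of the fruit fly *Drosophila melanogaster*. The flies ate normal food or food with pentylenetetrazole (PTZ), a drug that provokes seizures, and levetiracetam (LEV), an antiepileptic drug. Per the labels' protocols, the food held 8 mg/ml PTZ and 5 mg/ml LEV, and vials held 30 flies. Heads were taken after 12 h on both drugs, after 2 days on both drugs, or at 7 days, after 4 days on both drugs and 3 days on PTZ alone. The series design text in one place names LEV as the food of the last 3 days, while the treatment protocols of all 7-day samples and the titles of both dye-swapped ones name PTZ, which is the reading used here. Age is labelled as 3 to 4 days, while the growth protocol adds 10 to 11 days of maintenance, so age is left open.

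Each of the 12 arrays compared the RNA of 1 treated pool with that of the control pool of its own parallel set. The labels call the 4 arrays of a time 4 biological replicates. Replicates 1 and 2 of each time carried the treated sample in Cy5, and replicates 3 and 4 carried it in Cy3. Source names of 2 arrays (7 d replicate 1 and 2 d replicate 4) call both channels untreated, and the channels' treatment protocols settled these. The dye-swapped arrays of 12 h and 7 d have no number in the labels and were numbered in deposition order, which pairs nothing.

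The deposited values are log2 ratios of the 2 dye channels, made by the authors. Per the series design text, cDNA arrays of the D12Kv1 design were scanned on a GenePix 4000A at 10 micrometres and quantified with GenePix Pro 6.0. The same text gives a ratio-based normalization in Acuity 4.0 that ignored spots with raw intensity under 100 and under 2 times the background. It then lists spot filters: under 3% saturated pixels, no bad flag, a pixel regression R2 of at least 0.6 and a signal-to-noise ratio of at least 3. It names a one-class test in SAM 3.0 on spots measured in at least 3 of the 4 replicates. The base of the logarithm was read from the highest value, 16.61, which 8 spots share and which equals log2 of the top of GenePix's ratio range. Scanner intensities were not used here, and signal over background per spot is unknown, so spots could not be weighed by their signal. The genome build behind the array's annotation is not given in the sources used here, and no coordinates are printed.

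The table held 27648 spots, taken as 13824 adjacent pairs of the same probe. In all 7609 annotated pairs both spots had the same annotation, while for pairs without a symbol the pairing was assumed from position. The 2 spots of a pair were averaged. Of the probes, 7558 had 1 gene symbol in the platform annotation, 51 had several and 6215 had none. Symbols were updated through the entrez identifier with the names of RefSeq's Release 6 plus ISO1 MT table, which held 7447 of the 7558, and the file's symbol was kept for the rest. Probes with several symbols or none were tested but not named. A gene with several probes was represented by the probe measured on the most arrays, then by the first.

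The sources give no direction for the ratios: they could be Cy5 over Cy3 on every array, or already turned to treated over control. A rule set beforehand compared the correlation of arrays of opposite dye orientation within a time with that between times. A difference beyond 0.05 in either direction would have settled it. The difference was 0.0269 (Pearson), so direction stays open. As the rule states for that case, the dye-swapped arrays were turned, signs are conditional on Cy5 over Cy3, and the orientation as deposited was run as an alternative throughout. Scale was kept as deposited. Array medians were not at 0, so values are also given with each array centred on its median.

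For each time, probes with values on at least 3 of 4 arrays were tested for a mean log2 ratio other than 0 with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, intercept only, two-sided). Benjamini-Hochberg adjustment covered all probes of the time, with a threshold of 0.05. Differences between times were contrasts in 1 fit of all 12 arrays over probes on at least 3 arrays of every time. Of the 32 gene lists fixed beforehand, those with at least 5 measured genes at a time were tested with cameraPR at a preset correlation of 0.01, adjusted over lists and times. A list mean is the mean over arrays of the median of the list's genes on each array. Patterns of 2 lists were corrected for naming style before any list was tested. SDs are over arrays.

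The named genes followed a rule fixed before the data were examined. Per time and direction, it took the 10 strongest probes with 1 symbol past the threshold and with the same sign on every array. Where fewer than 5 passed, it took those and then the smallest p up to 5, said not to have passed. It added up to 4 members of the list of GABA and drug-target genes and of any passing list. Between times it took 5 genes per direction past the threshold, or the 3 of smallest p.

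Alternatives fixed beforehand were the other orientation, centring, scaling, dye terms, 12-array fits, stricter and looser filters, a SAM-type statistic over 16 sign flips, array weights, single orientations, a replicate block and leaving out each array. Averaging of duplicate spots, fits of probes with 1 symbol, agreeing duplicates, robust regression, combined settings, a fit over probes on at least 9 arrays and the test of measured shares were chosen after seeing the data. No pair of arrays was near identical: at most 0.288% of probes lay within 0.001 log2 of each other.

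The fits were tested on simulated data with the spread of centred arrays, the real missing values and 200 changed probes, without shifts of whole arrays. The reported tests used uncentred values. Their median SD over probes was 0.77 at 12 h, 0.83 at 2 d and 1.04 at 7 d, against 0.62, 0.72 and 0.79 centred. The reported fit at 7 d called no probe of a size under 2.30. The recovered shares can thus overstate the sensitivity of the reported tests. Of probes changed by 1 log2 unit, the test recovered 31.3% at 12 h, 22.4% at 2 d and 11.9% at 7 d. At 2 log2 units it recovered 62.7%, 52.2% and 65.7%. For the contrasts over 658 probes, a difference of 2 log2 units was recovered for 26.9% (12 h to 2 d), 32.8% (12 h to 7 d) and 31.3% (2 d to 7 d). Figures were drawn with matplotlib.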

Results

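Head RNA of drug-fed flies was set against that of control flies on 12 arrays, 4 per time. The 3 groups were PTZ+LEV for 12 h, PTZ+LEV for 2 days, and PTZ+LEV for 4 days followed by PTZ alone to day 7. Few spots had a value. At 12 h the replicates held 2091, 2813, 5213 and 7372 of 27648 spots. At 2 d they held 2017, 2020, 1868 and 1434, and at 7 d they held 1394, 2165, 2730 and 14042. Median deposited log2 ratios in replicate order were -0.08, 0.85, -0.69 and -0.56 at 12 h, -0.20, -0.44, -0.08 and -0.17 at 2 d, and -0.67, -0.63, 0.74 and -0.55 at 7 d. Duplicate spots within an array correlated at a Pearson r of 0.0957 to 0.496 across probes, and on one array 40.8% of pairs differed by over 1 log2 unit.

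**Figure D1:**
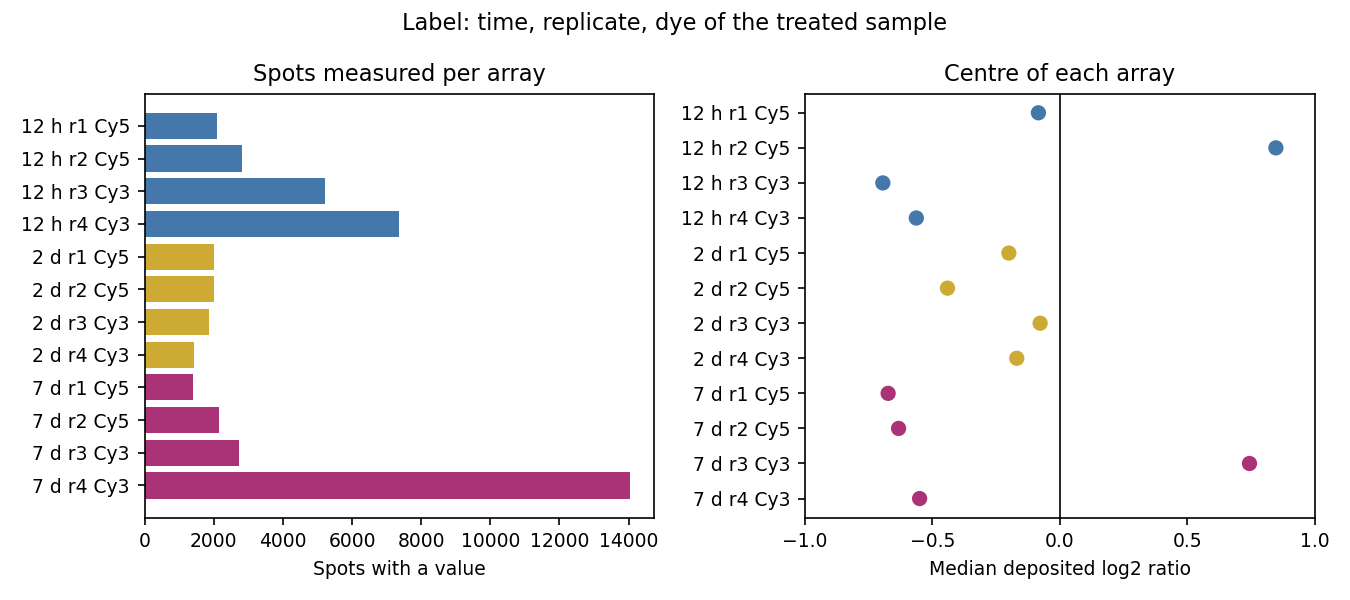
Left, bars of the number of spots with a value on each array; right, points of the median deposited log2 ratio of each array, coloured by time and labelled by replicate and dye of the treated sample. Replicate 4 at 7 d had 14042 spots, and medians ran from -0.69 to 0.85.

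Arrays resembled one another little. Across probes, which are not independent replicates, Pearson correlations of deposited ratios ran from -0.0691 to 0.341 over all pairs. Arrays of opposite dye orientation averaged 0.112 within a time and 0.0855 between times, and arrays of the same orientation averaged 0.110 and 0.105. By the rule set beforehand, these means over all times did not settle whether the deposited ratios are Cy5 over Cy3 or treated over control. The times differed: within 2 d, arrays of opposite orientation averaged 0.223, against 0.103 for opposite pairs of a 2 d array with another time, while the same means were 0.0487 and 0.0774 for 12 h and 0.0655 and 0.0764 for 7 d. This view by time was chosen after the data were seen. Signs assume Cy5 over Cy3, with dye-swapped arrays turned to treated over control. Replicates 1 and 2 of each time, with the treated sample in Cy5, read the same way under both possibilities, so their centred means are given separately for the genes named at each time. Centred values are relative to the median of each array. Centring moved the median over tested probes from 0.47 to -0.05 at 12 h, from -0.17 to -0.06 at 2 d and from -0.23 to 0.11 at 7 d.

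**Figure D2:**
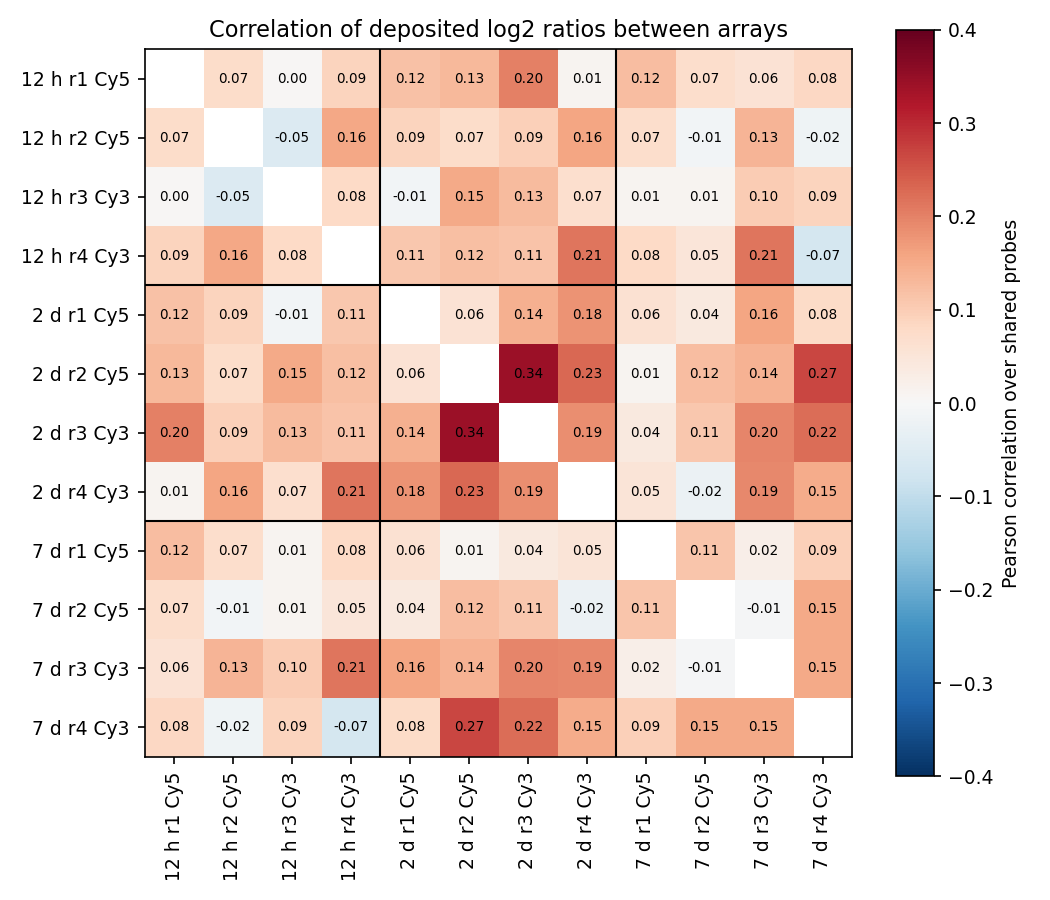
Heat map of the Pearson correlation of deposited log2 ratios between each pair of the 12 arrays over the probes both measured; labels give time, replicate and dye of the treated sample, and black lines part the times. Correlations ran from -0.07 to 0.34, and the pairs within 2 d averaged 0.189, against 0.0581 within 12 h and 0.0876 within 7 d.

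The comparison at 12 h asked which genes differed early on both drugs. The positive end held mRpS34, a mitochondrial ribosomal protein gene, at a log2 ratio of 1.53 ± 0.60 (SD, n = 4 arrays), and RpL15, of the large cytosolic ribosomal subunit, at 1.02 ± 0.36 (n = 4). Cyp313a1, a cytochrome P450 gene, lay at 1.31 ± 0.93 (n = 4), CG11089 at 1.30 ± 0.63 (n = 4), and Idgf6, a secreted chitinase-like growth factor gene, at 1.39 ± 0.53 (n = 3). All 5 were above 0 on every array that measured them. The negative end held Nckx30C, a sodium, calcium and potassium exchanger gene, at -0.16 ± 0.29, Picot, a phosphate cotransporter gene, at -0.33 ± 1.29, and CG2076, CG18809 and CG7781 at -0.78 ± 2.05, -0.67 ± 1.48 and -0.41 ± 1.37 (n = 4 each). None of these genes passed the test. The median over all 1283 probes was itself 0.47. After centring, mRpS34 stood at 1.03 ± 0.31, CG11089 at 0.80 ± 0.50, Cyp313a1 at 0.81 ± 0.75, Idgf6 at 0.69 ± 0.53 and RpL15 at 0.51 ± 0.22. The negative genes stood further from 0, with Nckx30C at -0.67 ± 0.17, Picot at -0.84 ± 1.36, CG2076 at -1.29 ± 2.22, CG18809 at -1.18 ± 1.59 and CG7781 at -0.92 ± 1.43. On the Cy5-treated arrays alone, centred means were 1.17 for mRpS34, 0.98 for CG11089, 0.69 for RpL15, 0.58 for Cyp313a1, 0.33 for Idgf6, -0.56 for Nckx30C, -1.75 for Picot, -0.46 for CG18809 and -0.16 for CG7781, while CG2076 stood on the other side at 0.61. Leaving out 1 array moved the positive genes little, with the lowest means at 1.31 for mRpS34, 1.12 for CG11089, 1.09 for Idgf6, 0.89 for Cyp313a1 and 0.86 for RpL15. The negative genes ranged up to 0.05 for CG18809, and from -1.39 to -0.17 for CG2076, -0.79 to 0.24 for CG7781, -0.71 to 0.21 for Picot and -0.27 to -0.04 for Nckx30C. With the orientation as deposited, centred mRpS34, CG11089 and RpL15 stayed positive at 0.14 ± 1.22, 0.18 ± 1.03 and 0.18 ± 0.60, and Picot stayed negative at -0.92 ± 1.29. The others changed sign, with Idgf6 at -0.47 ± 0.81, Cyp313a1 at -0.23 ± 1.17, Nckx30C at 0.11 ± 0.78, CG2076 at 1.90 ± 1.52, CG18809 at 0.72 ± 1.92 and CG7781 at 0.76 ± 1.55.

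In limma, 0 of 1283 probes passed at 12 h, with 110 at an unadjusted p under 0.05 where 64.2 were expected by chance. With arrays centred, 0 passed and 58 were under 0.05, below the number expected. A SAM-type statistic called 1 probe. The adjusted p of mRpS34, CG11089, Idgf6, Cyp313a1 and RpL15 was 0.478. Fitted over the 341 probes with 1 symbol, a setting chosen after the values were seen, 5 genes passed. They were mRpS34, CG11089, Cyp313a1, nahoda (2.41 ± 2.74, n = 3) and Fie (1.38 ± 1.88, n = 4). Their p values followed size and number of arrays rather than SD. The gene nahoda, with the largest SD, had the smallest adjusted p in limma (4.95e-06), against 0.00501 for mRpS34. Fie lay above 0 on 3 of 4 arrays. Once arrays were centred, 0 of the 341 passed and 24 had an unadjusted p under 0.05 against 17.1 expected by chance.

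**Figure D3:**
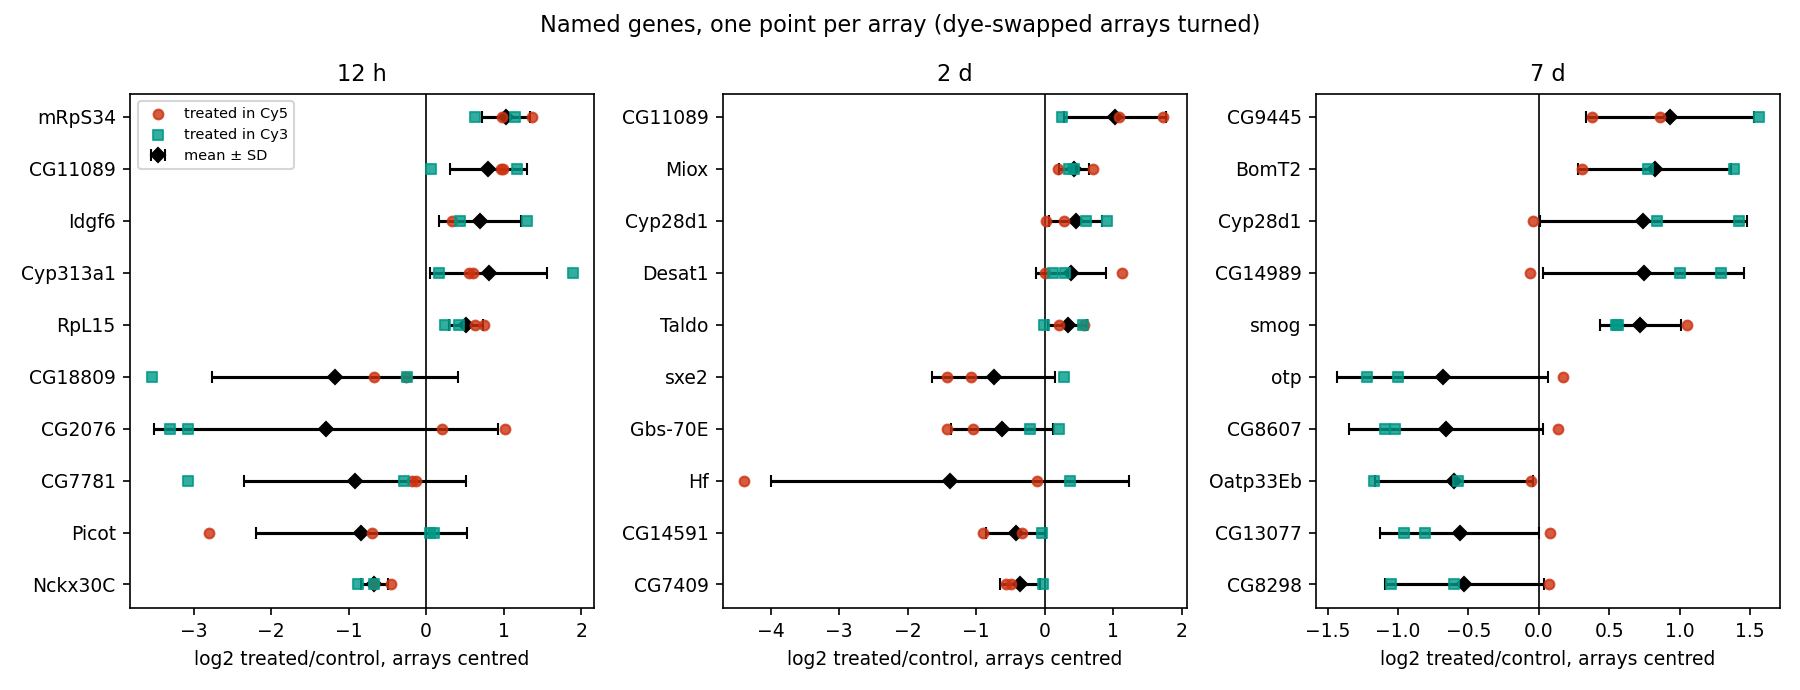
Centred log2 ratios of treated over control for the named genes at each time; circles are arrays with the treated sample in Cy5, squares are turned dye-swapped arrays, and diamonds with bars are the mean ± SD over 3 or 4 arrays. At 12 h mRpS34 was positive on every array, while none of the genes shown passed the test.

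The comparison at 2 d covered flies kept on both drugs. The positive end held CG11089 at 0.83 ± 0.48 (n = 3), Miox, the myo-inositol oxygenase gene, at 0.33 ± 0.38, Cyp28d1, a cytochrome P450 gene, at 0.35 ± 0.66, Desat1, a fatty acid desaturase gene, at 0.29 ± 0.56, and Taldo, the transaldolase gene of the pentose phosphate pathway, at 0.23 ± 0.34 (n = 4 each). The negative end held sxe2, a lipase gene, at -0.93 ± 1.15 (n = 3), Gbs-70E, a glycogen-binding phosphatase subunit gene, at -0.72 ± 1.02 (n = 4), Hf at -1.57 ± 2.85, CG14591 at -0.61 ± 0.69 and CG7409 at -0.55 ± 0.54 (n = 3 each). None passed. On the Cy5-treated arrays alone, centred means were 1.41 for CG11089, 0.45 for Miox, 0.15 for Cyp28d1, 0.57 for Desat1, 0.39 for Taldo, -1.25 for sxe2, -1.23 for Gbs-70E, -2.25 for Hf, -0.61 for CG14591 and -0.53 for CG7409. Leaving out 1 array moved both ends. The positive genes ranged from 0.61 to 1.09 for CG11089, 0.26 to 0.51 for Miox, 0.11 to 0.61 for Cyp28d1, 0.07 to 0.53 for Desat1 and 0.07 to 0.31 for Taldo. The negative genes ranged from -1.57 to -0.47 for sxe2, -1.08 to -0.34 for Gbs-70E, -2.57 to 0.06 for Hf, -0.93 to -0.25 for CG14591 and -0.85 to -0.32 for CG7409, each at its smallest size without replicate 2. CG11089 and Cyp28d1 were also on the positive side at 12 h, Cyp28d1 with 1.07 ± 0.88 (n = 4), and neither passed there. With the orientation as deposited, centred Cyp28d1 turned to -0.31 ± 0.55, Miox lay at 0.03 ± 0.53 and Taldo at 0.05 ± 0.47, and no other of the 10 genes changed sign.

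In limma, 0 of 1001 probes passed at 2 d, with 17 at an unadjusted p under 0.05 against 50.1 expected by chance, and the SAM-type statistic also called 0. The smallest adjusted p was 0.966. Of the 1001 probes, 196 had 1 gene symbol. As deposited and centred, 133 probes had an unadjusted p under 0.05, of which 8 had 1 symbol, and 0 passed. The number with 1 symbol depended on the probes fitted together. In a centred fit of the 196 alone, chosen after the values were seen, 32 were under 0.05 as deposited, against 9.8 expected by chance. With dye-swapped arrays turned, 4 were, and 0 passed in either orientation. Of 740 probes on all 4 arrays, 217 (29.3%) had the same sign on every array as deposited and centred. With dye-swapped arrays turned, 34 (4.6%) did. The first share lay above and the second below what random signs give. The 2 d means and the reported test are in the turned orientation, the one with the lower share. Ratios already turned by the authors and a dye effect of each probe would both give this, so the direction stays open.

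The comparison at 7 d covered flies moved from both drugs to PTZ alone. The positive end held CG9445 at 0.68 ± 1.26, BomT2, a bomanin gene of the immune response, at 0.55 ± 1.22, Cyp28d1 at 0.46 ± 1.05, CG14989 at 0.45 ± 1.15 and smog, which encodes a G protein-coupled receptor, at 0.44 ± 0.64 (n = 3 each). The negative end held otp, a homeobox gene, at -0.96 ± 0.69, CG8607 at -0.94 ± 0.72, Oatp33Eb, an organic anion transporter gene, at -0.88 ± 0.38, CG13077 at -0.84 ± 0.76 and CG8298 at -0.80 ± 0.90 (n = 3 each). None of the 10 genes passed, and each had an adjusted p of 0.997 in limma. The negative genes lay below 0 on all 3 arrays that measured them, but the median of their only Cy5-treated array, replicate 2, was -0.63, and after centring that array held otp at 0.17, CG8607 at 0.13, CG13077 at 0.08, CG8298 at 0.07 and Oatp33Eb at -0.06. On the Cy5-treated arrays, centred values of the positive genes were 0.61 for CG9445 (n = 2), and 0.31 for BomT2, -0.04 for Cyp28d1, -0.07 for CG14989 and 1.05 for smog (n = 1 each). After centring, otp stood at -0.68 ± 0.75, Oatp33Eb at -0.60 ± 0.56, smog at 0.72 ± 0.29, BomT2 at 0.82 ± 0.54 and CG9445 at 0.93 ± 0.60. Without centring, the positive end rested on replicate 4, the array with 14042 spots, whose deposited median was -0.55 before turning. Without that array, CG9445 at 7 d stood at -0.04, BomT2 at 7 d at -0.15, CG14989 at 7 d at -0.09, Cyp28d1 at 7 d at 0.00 and smog at 7 d at 0.12. After centring, replicate 4 was the highest array for CG9445 (1.56) and BomT2 (1.39) only. Replicate 3 was highest for Cyp28d1 (1.42) and CG14989 (1.30), and replicate 2 for smog (1.05). Also without centring, the negative genes were smallest in size without replicate 3, whose deposited median was 0.74 before turning. They then stood at -0.56 for otp, -0.52 for CG8607, -0.66 for Oatp33Eb, -0.41 for CG13077 and -0.31 for CG8298. After centring, replicate 4 was the lowest array for otp, CG8607 and Oatp33Eb, and replicate 3 for CG13077 and CG8298. With the orientation as deposited, all 10 genes changed sign after centring, among them otp at 0.80 ± 0.55, Oatp33Eb at 0.56 ± 0.62, BomT2 at -0.62 ± 0.86 and smog at -0.02 ± 0.93.

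In limma, 10 of 865 probes passed at 7 d, 1 above and 9 below 0 with dye-swapped arrays turned, and none of them has a single gene symbol. As deposited and centred, 4 of the 10 changed sign. Their mean log2 ratios had sizes of 2.30 to 3.35, with SDs of 0.31 to 5.04 over arrays, and 5 had the same sign on every array. With arrays centred, 0 passed (smallest adjusted p 0.923) and the median size of the 10 went from 2.85 to 2.48. With the orientation as deposited, or without replicate 4, 0 passed. Of the 865 probes, 142 had 1 gene symbol. In a centred fit of these alone, chosen after the values were seen, 25 had an unadjusted p under 0.05 as deposited. With dye-swapped arrays turned, 12 did, against 7.1 expected by chance, and 0 passed in either orientation.

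**Figure D4:**
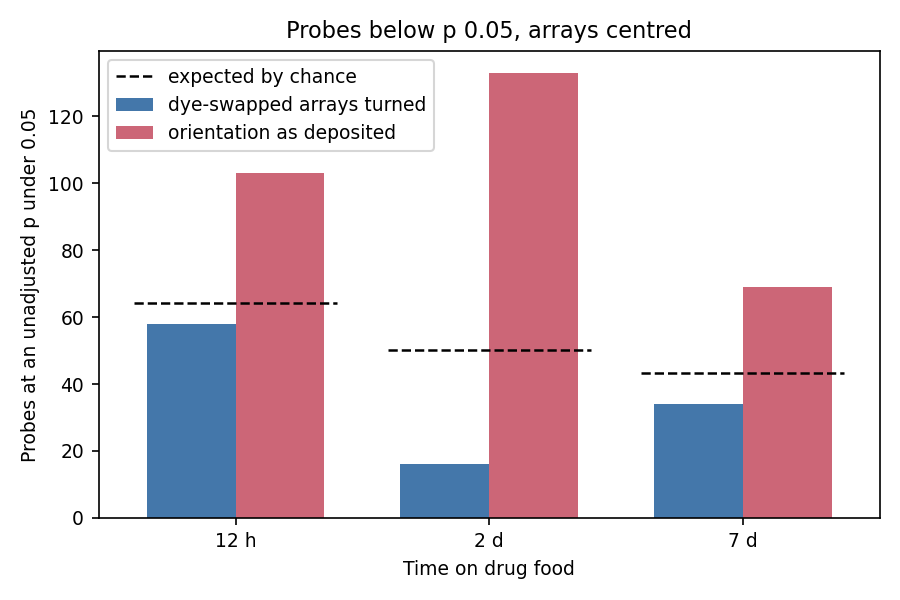
Bars of the number of probes at an unadjusted p under 0.05 in limma at each time, with arrays centred, for dye-swapped arrays turned and for the orientation as deposited; dashed lines mark the number expected by chance. At 2 d the counts were 16 turned and 133 as deposited, against 50.1 by chance.

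PTZ acts on GABA-gated chloride channels and LEV on a synaptic vesicle protein. The array held 7 genes of the list of GABA and drug-target genes, none of which encodes that vesicle protein. Among the 7, 2 had values on at least 3 arrays of a time. Of these, GluClalpha, a glutamate-gated chloride channel gene, had 3 arrays at 12 h, with a log2 ratio of -0.07 ± 0.42 and -0.51 ± 0.74 after centring, or -0.66 on the Cy5-treated arrays. Gad1, the glutamate decarboxylase gene that makes GABA, had 3 arrays at 7 d, with -0.40 ± 0.47, and turned to 0.28 ± 0.52 after centring, or -0.01 on the Cy5-treated arrays, and stood at -0.30 ± 0.50 centred in the orientation as deposited. Leaving out 1 array gave -0.27 to 0.15 for GluClalpha and -0.67 to -0.23 for Gad1. Neither passed (adjusted p = 0.936 and 0.997 in limma). Lcch3, a GABA receptor subunit gene, was measured on 2 of the 12 arrays, Rop on 1, and Gat, GABA-B-R3 and Ca-alpha1D on 0.

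Gene lists were on the side of 0 where the median of all probes lay at 12 h and 2 d. At 12 h all 16 measured oxidative phosphorylation genes were above 0, with a list mean of 0.55 ± 0.41 (SD, n = 4 arrays), and 0 passed. ATPsynbeta, of the mitochondrial ATP synthase, lay at 1.06 ± 0.65, ATPsynO at 0.66 ± 0.31 and SdhD, of succinate dehydrogenase, at 0.63 ± 0.36. All 7 cytosolic ribosomal protein genes were above 0 as well, with a list mean of 0.63 ± 0.41, RpL27 at 0.71 ± 0.28 and RpS7 at 0.59 ± 0.40. The 6 phototransduction genes had a list mean of 0.70 ± 0.68, with inaC, an eye protein kinase C gene, at 1.16 ± 0.79 and trpl, a light-gated channel gene, at 1.02 ± 1.03. The 5 translation factor genes had a list mean of 0.69 ± 0.54. After centring, these list means were 0.04 ± 0.17 for oxidative phosphorylation, 0.12 ± 0.27 for ribosomal proteins, 0.20 ± 0.31 for phototransduction and 0.19 ± 0.30 for translation factors. With the orientation as deposited and centred, 10 of the 16 oxidative phosphorylation genes lay above 0, with a list mean of 0.06 ± 0.16, and so did 6 of 7 ribosomal protein genes (0.18 ± 0.22), 2 of 6 phototransduction genes (-0.03 ± 0.39) and 2 of 5 translation factor genes (-0.19 ± 0.30).

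At 2 d, all 9 oxidative phosphorylation genes lay below 0, with a list mean of -0.25 ± 0.46 and -0.15 ± 0.21 after centring, COX4 at -0.35 ± 0.57 and ND-20 at -0.39 ± 0.51. All 6 glycolysis genes lay below 0, with a list mean of -0.16 ± 0.79 and Gapdh1 at -0.36 ± 0.83. Of 5 fat body genes, 4 lay below 0, with a list mean of -0.14 ± 0.42. All 5 ribosomal protein genes lay below 0 with a list mean of -0.15 ± 0.29, although their test against other genes pointed up. At 7 d, 4 of 5 oxidative phosphorylation genes lay above 0, with a list mean of 0.07 ± 0.92 and 0.45 ± 0.52 after centring. As deposited and centred, all 5 lay below 0 at 7 d (-0.42 ± 0.55). In that orientation at 2 d, 8 of 9 oxidative phosphorylation genes (-0.09 ± 0.25), all 6 glycolysis genes (-0.31 ± 0.40), 3 of 5 fat body genes (-0.08 ± 0.16) and 2 of 5 ribosomal protein genes (0.07 ± 0.15) lay below 0. Of the 9 list tests with cameraPR, 0 passed, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.405. No member of any list passed in limma, and 0 did adjusted over the list alone. With an estimated correlation the adjusted p was 0.758 for all 4 lists that could be run, and fry gave adjusted p values from 0.158, or 0.147 for change in either direction.

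Between times, the genes of smallest p in the contrasts with 12 h included Cyp313a1 and mRpS34. Cyp313a1 went from 1.31 ± 0.93 (n = 4) at 12 h to -0.50 ± 0.99 (n = 4) at 2 d and -0.38 ± 0.82 (n = 3) at 7 d. mRpS34 stood at 1.53 ± 0.60 (n = 4), -0.42 ± 1.38 (n = 3) and -0.33 ± 0.82 (n = 3) at the 3 times. Idgf6 was at -0.09 ± 0.95 (n = 4) at 2 d, and Mpcp2, a mitochondrial phosphate carrier gene, went from 0.88 ± 0.67 at 12 h to -0.20 ± 0.76 at 7 d (n = 4 each). From 2 d to 7 d, Gbs-70E went from -0.72 ± 1.02 (n = 4) to 0.17 ± 1.33 (n = 3), BomT2 from -0.23 ± 0.50 (n = 4) to 0.55 ± 1.22 (n = 3), and CG9445 from -0.25 ± 0.98 to 0.68 ± 1.26 (n = 3 each). None of these differences passed in limma, with adjusted p of 0.842 for Cyp313a1 and mRpS34 from 12 h to 2 d, and 0.642 for mRpS34 from 12 h to 7 d. After centring, the difference from 12 h to 2 d was -1.21 for Cyp313a1, -1.26 for mRpS34 and -0.68 for Idgf6. From 12 h to 7 d it was -1.07 for mRpS34, -0.91 for Cyp313a1 and -0.20 for Mpcp2. All of these were smaller in size than without centring. From 2 d to 7 d the centred difference was 1.04 for Gbs-70E, 0.95 for BomT2 and 0.99 for CG9445. As deposited and centred, the difference from 12 h to 2 d was -0.33 for Cyp313a1, -1.10 for mRpS34 and -0.10 for Idgf6, and from 12 h to 7 d it was -0.30 for mRpS34, -0.10 for Cyp313a1 and -0.15 for Mpcp2. From 2 d to 7 d it was 0.26 for Gbs-70E, 0.32 for CG9445 and, with the sign changed, -0.52 for BomT2. Leaving out 1 array kept every sign, with the smallest sizes from 2 d to 7 d at 0.12 for Gbs-70E, 0.08 for BomT2 and 0.21 for CG9445.

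In all 3 contrasts, 0 of 658 probes passed in limma. Unadjusted p was under 0.05 for 35 (12 h to 2 d), 50 (12 h to 7 d) and 17 probes (2 d to 7 d), against 32.9 expected by chance. With arrays centred these counts were 20, 26 and 13, all below the number expected. Only 36 of the 658 probes had 1 gene symbol, and the genes named above were drawn from these, so the contrasts cover few identified genes. At 7 d, time and drug regimen changed together, so the contrasts with that group cover both.

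Mean log2 ratios of the times were nearly unrelated across probes when dye-swapped arrays were turned. Pearson correlations were 0.00848 between 12 h and 2 d over 855 probes, 0.0494 between 12 h and 7 d over 736, and 0.0311 between 2 d and 7 d over 688, with Spearman values of -0.0517, 0.0773 and -0.0195. Over probes with 1 gene symbol they were 0.214 (126 probes), 0.190 (70 probes) and 0.346 (43 probes). With the orientation as deposited, the correlations over all shared probes were 0.306, 0.226 and 0.307, and over probes with 1 gene symbol they were 0.208, 0.505 and 0.114. Only 7 d had calls, so lists of calls could not overlap. Probes are not independent replicates, and no p is given.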

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

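All tests of the 3 patterns were chosen after the data were seen, and all but the one on disagreeing duplicate spots after the pattern itself was seen. The counts of calls over other sign patterns and splits were set beforehand. A sample stood far from the other 3 of its group in 4 of 46 measures examined, where chance gives about 1 in 20 groups, or 2.3. Replicate 4 at 7 d had 14042 spots with a value, while the next array of its group had 2730. Replicate 3 at 7 d had a median deposited log2 ratio of 0.74, while its group's others lay between -0.67 and -0.55. Miox at 2 d had a log2 ratio of -0.24 on replicate 2, and 0.51 on the nearest other array. The ribosomal protein genes at 2 d had a median of -0.58 on replicate 2, and -0.03 on the nearest other array. No tested list had every array on one side of 0 at one time and on the other side at another.

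Of 124 genes measured at both 12 h and 2 d, 6 lay above 0 on every array at 12 h and below 0 on every array at 2 d, where random signs give 0.75 in this order. This search was widened to all genes after the results were seen. The differences of the means were -0.94 for CG10863, -0.68 for CG3713, -1.02 for Sesn, -1.11 for Prp18, -0.70 for ATPsynB and -1.08 for Pis. With arrays centred, 0 of the 6 kept this and 3 other genes lay on opposite sides on every array, where random signs give 1.5 in either order, so the array medians could carry it, as for the oxidative phosphorylation genes with their centred difference of -0.20. The difference was in limma's contrast for Sesn and Pis alone, where neither passed (adjusted p = 0.864 each), and was not tested for the other 4. Without centring, no gene did so between 12 h and 7 d (69 genes) or 2 d and 7 d (42 genes).

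A component common to all 12 arrays, whatever the dye of the treated sample, was present in the deposited ratios. This fit, over 843 probes on at least 9 arrays, used values with each array centred on its median in both orientations. In it, limma called 29 in the orientation as deposited (186 at an unadjusted p under 0.05, 42.2 expected by chance). It called 0 once dye-swapped arrays were turned (38 unadjusted). None of the 29 has a single gene symbol. Leaving out disagreeing duplicate spots left 0 of the 29 called, but so did 20 random draws that removed as many values, the median size stayed at 1.33 after 1.28 and all 29 kept their sign, so noisy spots stay undecided. A treatment effect in ratios already turned by the authors, alike at all times, and a dye effect of each probe cannot be told apart here, since both predict alike correlations for both orientations: opposite orientations within a time minus between times gave 0.0269 (0.120 at 2 d, -0.0287 at 12 h and -0.0108 at 7 d), and opposite minus parallel orientations between times gave -0.0193. Probes with 1 gene symbol passed at an unadjusted p under 0.05 in 10.6% of 104 and the others in 23.7% of 739 (Fisher's exact test, two-sided, p = 0.00223), a difference whose cause was not tested. That test takes probes as independent, which they are not on the same 12 arrays, so its p can be too small. Both shares come from 1 fit of all 843 probes.

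The 10 unnamed probes called at 7 d have a candidate explanation in the estimate of the spread. limma took the spread as common to all 865 probes there, and the called probes had a median SD of 3.88 against 1.04 over all probes, 3.72 times as much, with 0 called in the fit of all 12 arrays. Arrays off centre do not account for the sizes, since the median size was 2.48 after centring and 2.85 before, with all 10 on the same side; the centred fit, with 0 calls, no longer took the spread as common (prior degrees of freedom 3.33). The 8 sign patterns of 4 arrays are too few for a share under 0.05: the real pattern gave 10 calls, 1 of the 8 gave as many, and the highest other gave 8. A treatment effect on these probes stays open and untested.

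Oxidative phosphorylation genes lay above 0 at 12 h (16 of 16) and below 0 at 2 d (9 of 9). Array medians off 0 are a candidate explanation, as the difference of the list means from 12 h to 2 d was -0.80 without centring and -0.20 with arrays centred. After centring, 13 of 16 genes were above 0 at 12 h and 9 of 9 below 0 at 2 d, and with the orientation as deposited these were 10 of 16 and 8 of 9, so a smaller drug-related shift stays open. The difference itself was not tested beyond these values.

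At 12 h and 2 d all 8 sign patterns gave at least the real count of 0 calls, with a highest other count of 1 and 0, and all 8 gave at least the 0 lists of the real pattern, with a highest other of 0; 8 patterns are too few for a share under 0.05. Between times, the real count was 0 in each contrast, so 35 of 35 splits of the 8 arrays reached it by construction and tell nothing about chance; the highest other split gave 0 (12 h and 2 d), 0 (12 h and 7 d) and 2 calls (2 d and 7 d). At an unadjusted p under 0.05, a measure taken up after the counts were seen, 13, 7 and 30 of the 35 splits gave at least the real 35, 50 and 17 probes. The highest other splits gave 102, 142 and 104, several times the real counts. For 12 h and 2 d and for 2 d and 7 d that split followed the dye of the treated sample. In turned ratios, a split by dye picks up whatever the deposited ratios share over both orientations. That would be a treatment effect if they were already treated over control, so its cause cannot be told apart here. With a dye term in the fit, 0 probes were called in each contrast, with 42, 63 and 22 at an unadjusted p under 0.05.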

How the results depend on the processing

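Settings on 1-symbol probes, agreeing duplicates, robust regression or combined choices were chosen after seeing the data, and the cause of the changes was not tested except where stated. Of 127 counts of calls under alternatives, 94 equalled the reported count, each of them 0 where 0 was reported. No alternative at 7 d equalled its 10 calls. Among 810 values of named genes, 728 kept sign and call, though not size. No named gene was called in the reported fits, so keeping the call says little. A further 79 changed sign without a call, mostly with the other orientation. Another 3 were called (mRpS34, CG11089 and Cyp313a1 at 12 h, 1-symbol probes alone, where p did not follow the SDs), with none reversed. At 12 h (0 calls) the count was 1 with the other orientation, in the 12-array fit, with a shared dye term, with the SAM-type statistic and with duplicates within 1 log2 unit, 7 with a dye term in the 4-array fit, 12 on the Cy5-treated arrays alone, 5 on 1-symbol probes, and 0 to 6 leaving out 1 array (6 without replicate 3, 2 without replicate 4). At 2 d (0 calls) it was 6 on the Cy5-treated arrays alone and 0 leaving out any array. At 7 d (10 calls) it was 0 with the other orientation (centred or not), centring, scaling, the 12-array fit, either dye term, all 4 arrays measured, the Cy5-treated arrays alone, robust regression and 1-symbol probes in all 3 settings; it was 12 with array weights (9 shared), 8 with at least 2 of 4 arrays measured (8 shared), 2 with the SAM-type statistic (1 shared), 2 with agreeing duplicates (both shared), 6 on the Cy3-treated arrays alone (3 shared), and 0 to 6 leaving out 1 array (6 without replicate 1, 5 without replicate 2, 6 without replicate 3, 0 without replicate 4). Correlations between times, in the order 12 h with 2 d, 12 h with 7 d and 2 d with 7 d, were 0.306, 0.226 and 0.307 with the other orientation, -0.207, -0.115 and -0.276 for Cy5-treated arrays of the earlier against Cy3-treated arrays of the later time, -0.199, -0.0587 and -0.0709 for the reverse, and -0.0269 to 0.0516, 0.0115 to 0.0871 and -0.0533 to 0.101 leaving out 1 array. Contrasts between times and list tests stayed at 0 in every setting run. The replicate block gave all dye-swapped arrays the same level and replicates 1 and 2 a level each, shared over times. With it, 0 probes were called in each contrast, with 42, 61 and 21 at an unadjusted p under 0.05. Outside that setting, replicates of equal number at different times were not treated as pairs. Only replicates 1 and 2 were compared for this. Their deviations from the mean of the time correlated at 0.000535 to 0.220 for equal numbers and at 0.0731 to 0.166 for unequal ones. Signal over background is not given per spot. The simulated test, at the smaller spread of centred arrays, recovered 11.9% to 31.3% of changes of 1 log2 unit within a time.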

Other observations

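Genes with values were unevenly spread over gene groups. This test of measured shares was chosen after seeing the data and takes genes as independent. Of 6793 genes with a probe, 466 (6.86%) had values on at least 3 of 4 arrays at some time. Oxidative phosphorylation genes stood out with 19 of 39 measured (48.7%; Fisher's exact test, two-sided, adjusted p = 3.32e-11 over 32 lists), among them ATPsynbeta, COX4 and ND-51. Glycolysis followed with 7 of 15, including Gapdh1, Tpi and Eno (adjusted p = 0.000289), and cytosolic ribosomal proteins with 10 of 23, including RpL15 and RpL27 (adjusted p = 1.7e-05). Some lists of eye, nerve and fat tissue also had higher shares. Phototransduction had 6 of 17 measured, with inaC, inaD, trpl, Arr1, Galphaq and rdgC. The fat body and yolk list had 6 of 17, with Yp2, apolpp and FASN1 (adjusted p = 0.00416 each). At 12 h, 2 d and 7 d, 6, 2 and 1 phototransduction genes and 2, 5 and 0 fat body and yolk genes were measured. Over all genes, 335, 190 and 141 were tested at those times, and shares were not compared between times by a test. The synaptic vesicle list had 6 of 18, with unc-13, Rab3 and alphaSnap (adjusted p = 0.00491), and odorant-binding genes had 6 of 25, with Obp56d and Obp19d (adjusted p = 0.0266). Muscle genes had 4 of 12, with Act88F and Mlc2 (adjusted p = 0.0278), and translation factors 6 of 29 (adjusted p = 0.044).

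Other lists did not pass this test. The list of GABA and drug-target genes had 2 of 7 measured (28.6%, adjusted p = 0.209), and heat shock genes and neurotransmitter receptors and transporters had 4 of 21 each (19.0%, adjusted p = 0.15). Cytochrome P450 genes had 5 of 72 measured, testis and accessory gland genes 2 of 18, midgut digestion genes 1 of 24, glial genes 1 of 16 and cuticle genes 0 of 37. The amino acid transporter gene Eaat2 and the thioredoxin gene TrxT had a value on all 12 arrays. Probes measured most widely were mostly without a gene symbol here: 8 of the 369 on all 12 arrays (2.17%) had 1 symbol, against 66.1% of the 4250 probes measured on 1 array.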
